A study of Homo sapiens with 5 samples.

How the data were processed

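Single-cell RNA was measured in 5 libraries of the MDA-MB-468 cell line, 1 per group. Per the labels' protocols, cells were dissociated with trypsin and libraries of polyadenylated RNA were made with the 10x 3' version 3.1 kit for a target of 10000 cells. The deposited values are UMI counts, whole numbers per gene and barcode for 36601 features. Reads were aligned to GRCh38 and counted with Cell Ranger 7.1.0, per the submitters' processing notes. The annotation release, and whether intronic reads were counted, are not given in the sources used here. Gene positions come from GENCODE 29 on GRCh38.

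Cells were kept with at least 1000 detected genes and at most 20% of UMIs from mitochondrially encoded genes. Doublets were not removed, and no clusters were made. The counts of kept cells were summed per library and scaled to CPM by the library's total. Each comparison used the genes at 10 CPM or more in at least 1 of its libraries, and a sum of 0 was replaced by a floor of 3 counts. Ratios are given on the log2 scale or as folds, with exact 95% intervals of the ratio (Clopper-Pearson, conditional on the sum of both counts). These cover counting error only.

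A total of 26 gene lists were written before the data were examined, as were the comparisons, the filters, the rule for naming genes and the 12 alternative settings. They cover fatty acid synthesis, cholesterol synthesis and uptake, ER chaperones and ER-associated degradation, the PERK-ATF4 stress response, fatty acid oxidation, lipid droplets and fatty acid uptake, phospholipids, LXR targets, S phase, G2/M phase, apoptosis and arrest, NRF2 targets, heat shock, hypoxia and glycolysis, the nuclear-encoded respiratory chain, mitochondrially encoded genes, ribosomal proteins, interferon response, NF-kB and cytokines, EGFR-MAPK feedback, immediate early genes, autophagy and lysosome, and markers of epithelial, basal epithelial, mesenchymal and other cells. A list's result is the median log2 ratio of its measured members, given for lists of at least 5. It is set beside the medians of 10000 random lists of the same size matched on mean expression in 20 bins.

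Genes were named by a fixed rule. For each comparison of an inhibitor or recovery library with untreated cells, the rule named the 10 highest and 10 lowest genes of at least 20 CPM that lay on the same side of both untreated libraries, ranked by the smaller ratio. The minimum could be met in that library or in either untreated one, so a named gene can lie below it in both libraries compared. For recovery against 72 h of inhibitor, and for the untreated libraries, it named the 5 highest and 5 lowest. Up to 4 members of each list with the largest ratios were added, together with ACACA, ACACB, HSPA5, DDIT3, ATF4 and XBP1. Clone-style, LINC and mitochondrial names were left out of the ranking. A selection of the named genes is printed.

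For counts per cell, each kept cell of at least 5000 UMIs was thinned at random to 5000 UMIs. Kept cells of fewer UMIs were left out. These were 5 at 0 h untreated, 10 at 6 h of inhibitor, 35 at 72 h untreated, 59 at 72 h of inhibitor and 75 in recovery. The share of cells above the 90th percentile of the 0 h untreated library was taken with its exact binomial interval. That interval leaves out the randomness of the thinning. Alternatives were no cell filter, a mitochondrial limit of 10%, leaving out the 5% of cells with most UMIs, median-of-ratios and trimmed-mean-of-M-values scaling, totals without mitochondrial and ribosomal protein genes, equal weight per cell, thinned cells, no expression minimum or one of 50 CPM, cells low in both cell cycle lists, and the other untreated library. Cells of at least 20000 UMIs and at most 10% mitochondrial UMIs were added after seeing the data.

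The steps were tested on simulated data for 72 h of inhibitor against 72 h untreated, with 9100 genes. All 200 genes given a known fold came out in the right direction, and intervals held the true fold for 93% of them. Of 8877 genes left alone, 0 differed more than 2-fold. Both simulated libraries were drawn from the same profile with counting error alone, so differences between real libraries were not simulated. The untreated libraries measured here had 7.04% of genes more than 2-fold apart. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9 were used.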

Results

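Single-cell RNA was counted in 5 libraries of MDA-MB-468, an established human triple-negative breast cancer cell line. PF0517515 is named in the study's title as an inhibitor of acetyl-CoA carboxylase (ACC), the enzyme that makes malonyl-CoA for fatty acid synthesis. There was 1 library of untreated cells at 0 h, 1 of cells given the inhibitor for 6 h, 1 given it for 72 h, 1 untreated for 72 h, and 1 of recovery cells after 72 h of the inhibitor. The labels give no dose, vehicle or length of recovery. With 1 library per group no difference could be set against a spread between samples, so no test is given. Every value below describes these libraries, and ranges in parentheses are exact 95% intervals of counting error alone.

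The 0 h untreated library held 3736 barcodes, of which 3705 cells were kept, with a total of 114350566 UMIs (unique molecular identifiers) and a median of 28980 per cell. The 6 h inhibitor library kept 3006 of 3016, with 106673213 UMIs and a median of 33712. The 72 h untreated library kept 2920 of 2995, with 93898612 UMIs and a median of 29232. In the 72 h inhibitor library, 1927 of 2057 were kept, with 85376888 UMIs and a median of 41573. The recovery library kept 3537 of 3679, with 102172847 UMIs and a median of 26540. The median share of a cell's UMIs from mitochondrially encoded genes was 5.63% at 0 h, 6.06% at 6 h of inhibitor, 6.17% at 72 h untreated, 3.31% at 72 h of inhibitor and 2.55% in recovery. Cells of fewer than 10000 UMIs made up 0.729%, 0.632%, 2.12%, 6.95% and 6.84% in the same order.

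The first comparison asked how cells after 72 h of ACC inhibition differed from untreated cells of the same time. Genes of the endoplasmic reticulum (ER) stress response were higher in the inhibitor library and genes of DNA synthesis and mitosis were lower. HSPA5, the main ER chaperone, was 2.63-fold (2.57 to 2.68) higher, at 340.4 against 129.6 CPM (counts scaled to the same library total), and DDIT3, which encodes the stress transcription factor CHOP, was 3.58-fold (3.47 to 3.69) higher. RRM2, a subunit of the enzyme that makes deoxynucleotides, was 6.81-fold (6.46 to 7.19) lower. The calprotectin genes S100A8 and S100A9 were 51.5-fold (49.6 to 53.4) and 10.2-fold (10.1 to 10.2) lower, while the stress gene GADD45G was 35.7-fold (33.3 to 38.3) higher.

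Of the drug's targets, ACACA (ENSG00000278540, GRCh38 chromosome 17, 37084988 to 37406818, minus strand) was 1.75-fold (1.68 to 1.84) lower, at 32.9 against 57.7 CPM. ACACB (ENSG00000076555, chromosome 12, 109116595 to 109268226, plus strand) stood at 2.6 against 3.5 CPM. HSPA5 (ENSG00000044574) lies on chromosome 9 at 125234853 to 125241330, and DDIT3 (ENSG00000175197) on chromosome 12 at 57516588 to 57521737. ATF4 (ENSG00000128272, chromosome 22, 39519695 to 39522685), the transcription factor of the PERK branch, stood at 256 against 256 CPM, and XBP1 (ENSG00000100219, chromosome 22, 28794555 to 28800597), that of the IRE1 branch, at 202 against 189.

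Of 23 measured genes for ER chaperones and ER-associated degradation, 18 were higher and 5 lower in the 72 h inhibitor library, with a median log2 ratio of 0.39. That median lay above 10000 of 10000 random lists matched on expression. The same list's median between the untreated libraries was 0.30, above 9821. HERPUD1, which takes part in ER-associated degradation, was 2.7-fold (2.64 to 2.76) higher, SEL1L, a scaffold of the same pathway, 2.17-fold (2.03 to 2.32) and the chaperone HYOU1 1.8-fold (1.71 to 1.89). Of 26 PERK-ATF4 stress genes 21 were higher, with a median of 0.41, also above 10000 random lists. Between the untreated libraries it was 0.73, likewise above 10000. PPP1R15A, which directs the dephosphorylation of eIF2-alpha, was 2.74-fold (2.62 to 2.86) higher, VEGFA 2.09-fold (2.01 to 2.18) and the stress protein gene NUPR1 2.06-fold (2.03 to 2.09). Against the 0 h untreated library in place of the 72 h one, these medians were 0.74 and 0.98.

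Fatty acid synthesis genes were lower in 12 of 14, with a median of -0.28 that lay above 1147 random lists, within their central 95%. Of all genes compared only 39% were higher, and median-of-ratios scaling moved the median of all genes by 0.25. FASN, the fatty acid synthase, was 1.99-fold (1.91 to 2.07) lower and TECR, which elongates very long fatty acids, 1.79-fold (1.76 to 1.82) lower, while SCD, which desaturates fatty acids, was 1.6-fold (1.52 to 1.68) higher. Cholesterol synthesis and uptake genes went both ways, 10 higher and 12 lower, with a median of -0.061 that turned to 0.17 with median-of-ratios scaling and to 0.16 with the trimmed mean of M values. Genes of lipid droplets and fatty acid uptake had a median of 0.15, above 9698 random lists and within their central 95%, with a few members far higher. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 13-fold (10.9 to 15.6) higher, PDK4, which blocks pyruvate oxidation, 9.41-fold (8.17 to 10.9), the droplet coat gene PLIN2 3.15-fold (3.03 to 3.27) and LPIN1, a phosphatidate phosphatase, 2.4-fold (2.23 to 2.6).

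S phase genes were lower in 37 of 38, with a median of -0.76 below every matched random list. Between the untreated libraries it was -0.63, likewise below every matched random list. G2/M genes were lower in 50 of 51, with a median of -0.93, also below every matched random list, beside 0.073. GINS2, part of the replicative helicase, was 3.0-fold (2.81 to 3.2) lower, the tubulin gene TUBB4B 3.22-fold (3.15 to 3.3) and CENPF, a kinetochore protein gene, 3.04-fold (2.97 to 3.12). Cells low in UMIs of both lists were 74.1% of the thinned cells at 72 h of inhibitor and 45.5% of those at 72 h untreated. Among them the G2/M median was -0.062. These cells were chosen by UMIs of the same list, so this value does not show where the -0.93 came from. Immediate early genes had a median of -1.43, below every matched random list, with NR4A1 8.82-fold (8.15 to 9.56), FOS 6.98-fold (6.7 to 7.28) and EGR1 4.81-fold (4.55 to 5.09) lower. Against the 0 h untreated library the immediate early median was -0.47, within the central 95% of random lists.

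Cytosolic ribosomal protein genes were higher in 29 of 30, with a median of 0.56 above 10000 random lists, led by RPL10 at 1.87-fold (1.86 to 1.88). Mitochondrially encoded genes had a median of -0.99, with 10 of 13 lower, and MT-ATP6, a subunit of ATP synthase, was 4.6-fold (4.57 to 4.63) lower. Nuclear-encoded respiratory chain genes were lower in 29 of 30, with a median of -0.37 above 112 random lists. The iron storage genes FTL and FTH1 were 3.94-fold (3.9 to 3.98) and 2.75-fold (2.74 to 2.75) higher, and HMOX1, which degrades haem, 3.51-fold (3.31 to 3.73). SQSTM1, the autophagy receptor p62, was 2.81-fold (2.77 to 2.85) higher.

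Among the other named genes, the snoRNA host transcript SNHG12 was 6.96-fold (6.69 to 7.25) higher, the stress cytokine gene GDF15 6.95-fold (6.49 to 7.45), NDRG1 9.03-fold (8.12 to 10.1), GPNMB 6.62-fold (6.15 to 7.12), the defensin gene DEFB1 5.84-fold (5.69 to 5.99), EPB41L4A-AS1 4.31-fold (4.22 to 4.4), CREBRF 4.19-fold (3.95 to 4.44) and the protease gene PRSS22 4.1-fold (3.95 to 4.26). The lowest included S100A7 at 17.8-fold (17.5 to 18.2), the matricellular gene CCN2 at 9.66-fold (8.72 to 10.7), the amino acid transporter gene SLC6A14 at 7.78-fold (6.84 to 8.87), ARHGEF39 at 7.25-fold (6.41 to 8.23), AGR2 at 8.62-fold (7.52 to 9.93), FGFBP1 at 6.72-fold (6.29 to 7.19) and the elastase inhibitor gene PI3 at 6.07-fold (5.69 to 6.49). Of 9346 genes at 10 CPM or more in at least 1 of both libraries, 9.33% lay more than 2-fold apart, beside 7.04% between the untreated libraries. With total counts 185 of them were higher and 687 lower, whereas with median-of-ratios scaling, which moved the median of all genes by 0.25, 380 were higher and 365 lower. The trimmed mean of M values gave 370 and 374, and totals without mitochondrial and ribosomal protein genes 291 and 595. Against the 0 h untreated library 751 genes were higher and 977 lower.

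EGFR-MAPK feedback genes had a median of -0.35 and epithelial genes one of -0.37, and fatty acid oxidation genes, with 11 of 15 lower, one of -0.32. Medians for interferon response, NF-kB and cytokine, and autophagy and lysosome genes were -0.25, -0.31 and 0.063, those for NRF2 targets and heat shock genes 0.027 and 0.0056, and each lay within the central 95% of its random lists. Medians of -0.020 for phospholipid genes, -0.059 for apoptosis and arrest genes, -0.026 for hypoxia and glycolysis genes and -0.10 for basal epithelial genes turned positive with median-of-ratios scaling. Against the 0 h untreated library, medians of -0.61 for cholesterol genes, -0.81 for basal epithelial genes, 0.66 for NRF2 targets, 0.56 for apoptosis and arrest genes, 0.55 for lipid droplet genes and 0.37 for autophagy genes lay outside that range. Of 49 printed genes, 20 had a fold that differed by more than 1.5 times against that library, the most for GDF15 at a log2 ratio of 5.87 in place of 2.80. LXR targets had too few measured members here, and in recovery against the 72 h inhibitor library their median was 0.46 over 5 genes, within the central 95% of random lists. For recovery against 72 h untreated cells it was 0.47, just outside that range, above 9772 lists. Mesenchymal genes had enough members at 6 h, with a median of 0.28 over 5 genes, above 5715 random lists. Of the markers of cells other than breast epithelium, fewer than 5 reached 10 CPM in each comparison, so no median was taken.

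**Figure D1:**
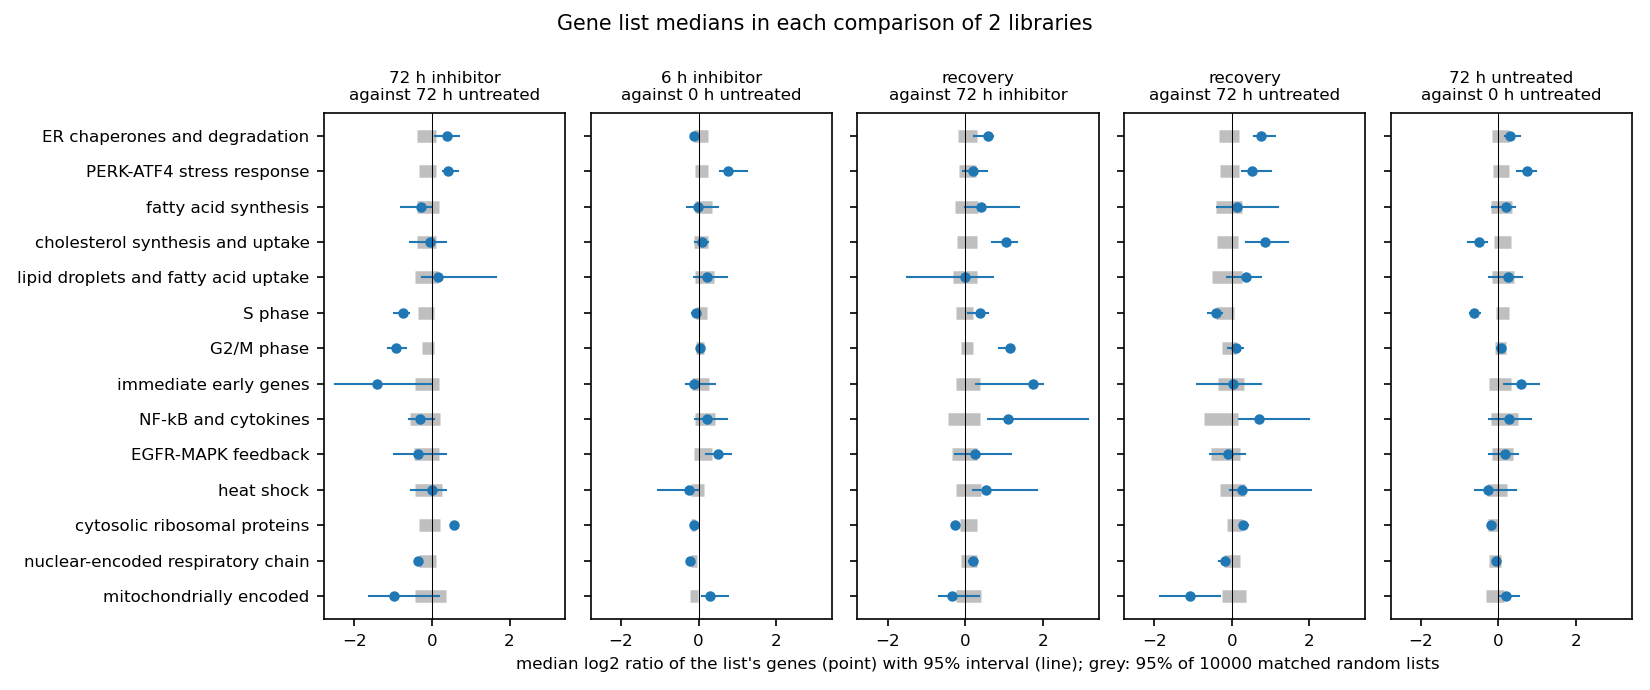
Median log2 ratio of 14 gene lists (points) with its 95% interval (blue lines) in 5 comparisons of 2 libraries each; grey bars hold the central 95% of 10000 matched random lists. The ER chaperone median was 0.39 at 72 h of inhibitor, -0.12 at 6 h and 0.75 in recovery against 72 h untreated cells.

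The second comparison set 6 h of inhibitor against untreated cells at 0 h and asked which differences were present early. There was no untreated library at 6 h, so the inhibitor could not be told apart from 6 h of culture. PERK-ATF4 stress genes were higher in 27 of 28, with a median of 0.77 above 10000 of 10000 random lists. STC2, a secreted stress protein gene, was 5.62-fold (5.23 to 6.04) higher, the glutathione-degrading enzyme gene CHAC1 5.22-fold (4.69 to 5.81), the stress sensor gene SESN2 4.77-fold (4.42 to 5.15), CTH, an enzyme of cysteine synthesis, 4.17-fold (3.72 to 4.69) and DDIT3 3.87-fold (3.68 to 4.06). ER chaperone genes were not higher: 15 of 20 were lower, with a median of -0.12 above 199 random lists, and HSPA5 stood at 75.4 against 74.8 CPM. HERPUD1 and XBP1 were 1.7-fold (1.64 to 1.77) and 1.53-fold (1.5 to 1.58) higher than at 0 h, but both were lower than in the 72 h untreated library. Against that library the PERK-ATF4 median was 0.19, within the central 95% of random lists, and the ER chaperone median -0.38.

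ACACA was 1.42-fold (1.37 to 1.48) higher and ACACB 1.3-fold (1.16 to 1.46) higher at 6 h, and ATF4 stood at 273 against 266 CPM. ACACA is among the 873 protein-coding genes of longest genomic span, which had a median log2 ratio of 0.48 in this comparison. It was also higher at 72 h untreated than at 0 h, while ACACB was lower there. Fatty acid synthesis genes split evenly, 7 higher and 7 lower, with a median of -0.0036. Within that list ACSS2, which makes acetyl-CoA from acetate, was 1.61-fold (1.54 to 1.69) higher and ME1, a source of NADPH, 1.42-fold (1.38 to 1.46). Cholesterol genes had a median of 0.10 (-0.071 with median-of-ratios scaling and 0.47 against the 72 h untreated library), with the sterol regulator SREBF2 1.67-fold (1.62 to 1.72) higher. EGFR-MAPK feedback genes were higher in 14 of 15, with a median of 0.50 above 9993 random lists, but one of 0.15, within their central 95%, against the 72 h untreated library. The growth factor genes HBEGF and AREG were 4.45-fold (3.94 to 5.05) and 2.02-fold (1.95 to 2.1) higher and the AP-1 gene FOSL1 2.58-fold (2.5 to 2.66). Basal epithelial genes were higher in 13 of 15 (median 0.51, or 1.43 against the 72 h untreated library), with the keratin genes KRT16 and KRT17 2.34-fold (2.27 to 2.41) and 2.29-fold (2.27 to 2.31) higher and EGFR 1.78-fold (1.77 to 1.78).

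Heat shock genes were lower in 11 of 13, with a median of -0.26 above 6 random lists; HSPA1A was 2.61-fold (2.52 to 2.7) and HSPA8 2.21-fold (2.19 to 2.23) lower. Against the 72 h untreated library the heat shock median was -0.11 and that of mitochondrially encoded genes 0.026, both within the central 95% of random lists. GCLC, the rate-limiting enzyme of glutathione synthesis, was 2.95-fold (2.87 to 3.02) and the thioredoxin reductase gene TXNRD1 1.82-fold (1.8 to 1.85) higher, while the NRF2 target list as a whole had a median of 0.090, or -0.080 with median-of-ratios scaling and -0.25 against the 72 h untreated library. GADD45A, a growth arrest gene, was 2.63-fold (2.57 to 2.68) higher. Mitochondrially encoded genes were higher in 12 of 13 (median 0.29), and nuclear-encoded respiratory chain genes were lower in 30 of 30 (median -0.22). In this comparison log2 ratios also went with the genomic span of a gene: the 873 protein-coding genes of shortest span had a median of -0.20 and as many of longest span one of 0.48, and the random lists were not matched on span. Hypoxia and glycolysis genes had a median of 0.26, but -0.048 over genes of at least 50 CPM. S phase and G2/M medians were -0.074 and 0.025; against the 72 h untreated library the S phase median was 0.57, and median-of-ratios scaling turned the G2/M median to -0.14.

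The other highest genes were HIF1A-AS3 at 4.2-fold (4.02 to 4.38), SAMD4A at 3.98-fold (3.74 to 4.22), NDRG1 at 3.84-fold (3.51 to 4.2), the potassium channel gene KCNQ5 at 3.23-fold (3.06 to 3.41), the tissue factor gene F3 at 2.76-fold (2.68 to 2.83), ANKRD1 at 2.74-fold (2.55 to 2.96), the histone deacetylase gene HDAC9 at 2.9-fold (2.76 to 3.04) and the transcription factor gene ETS1 at 2.41-fold (2.3 to 2.52). The lowest were the death ligand gene TNFSF10 at 3.31-fold (3.13 to 3.51), CD14 at 2.51-fold (2.34 to 2.69), HSPA1B at 2.07-fold (1.91 to 2.23), AGR2 at 2.01-fold (1.85 to 2.19), SYT12 at 1.86-fold (1.77 to 1.96), LY6D at 2.53-fold (2.38 to 2.7), MSMB at 1.81-fold (1.65 to 1.99), CITED4 at 1.8-fold (1.77 to 1.83) and CCDC160 at 1.77-fold (1.6 to 1.95). Of 9075 genes 2.13% lay more than 2-fold apart, 181 higher and 12 lower. Median-of-ratios scaling, which moved the median of all genes by -0.18, gave 97 and 32 and the trimmed mean of M values 110 and 22. Against the 72 h untreated library the excess turned, with 184 genes higher and 381 lower. In that comparison, 17 of 41 printed folds differed by more than 1.5 times, the most for TNFSF10 at a log2 ratio of -3.70 in place of -1.73.

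The third comparison asked what differed between recovery cells and cells still under the inhibitor at 72 h. Sterol synthesis genes, ER chaperone genes and G2/M genes were all higher as groups in the recovery library. MSMO1 and HMGCS1, enzymes of cholesterol synthesis, were 5.18-fold (5.02 to 5.35) and 3.92-fold (3.76 to 4.09) higher, and INSIG1, a sterol-regulated brake on that pathway, 4.71-fold (4.4 to 5.04). HSPA5 was 2.46-fold (2.43 to 2.49) higher again, at 838 CPM, and HERPUD1 2.82-fold (2.78 to 2.86). S100A8, S100A7 and S100A9, among the lowest under the inhibitor, were 24.9-fold (24.1 to 25.9), 9.76-fold (9.58 to 9.95) and 8.24-fold (8.19 to 8.3) higher.

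Cholesterol genes were higher in 21 of 22, with a median of 1.05 above 10000 random lists, and fatty acid synthesis genes in 12 of 14, with a median of 0.41 above 9932. FASN was 2.6-fold (2.5 to 2.71) higher, the elongase gene ELOVL5 2.99-fold (2.89 to 3.1), ACSS2 2.86-fold (2.75 to 2.96) and SREBF1, a master regulator of lipid synthesis, 2.1-fold (1.97 to 2.23). PLIN2 and ANGPTL4 were 2.85-fold (2.75 to 2.96) and 7.32-fold (6.42 to 8.38) lower, and ACACA stood at 33 against 32.9 CPM. ER chaperone genes were higher in 18 of 23, with a median of 0.59 above 10000 random lists; HSP90B1 was 1.9-fold (1.88 to 1.92) and PDIA4 1.76-fold (1.7 to 1.82) higher, and XBP1 stood at 196 against 202 CPM. PERK-ATF4 genes had a median of 0.21, above 8897 random lists and within their central 95%, with DDIT3 2.04-fold (2.0 to 2.07) and SESN2 2.94-fold (2.76 to 3.13) higher. The recovery library held 6.84% cells of fewer than 10000 UMIs and the lowest mitochondrial share of the 5.

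G2/M genes were higher in 50 of 51 (median 1.15) and S phase genes in 25 of 35 (median 0.38), with the mitotic kinase gene AURKB 3.43-fold (3.25 to 3.63) and RRM2 4.88-fold (4.62 to 5.16) higher. Immediate early genes had a median of 1.75 and NF-kB and cytokine genes one of 1.12, with 13 of 13 higher. ZFP36, which destabilises cytokine transcripts, was 6.64-fold (6.29 to 7.02) higher, and TNF stood at 16 against 0.316 CPM. MYC was 4.18-fold (4.03 to 4.33) lower. Heat shock genes were higher in 12 of 13 (median 0.54), with HSPA1A 4.54-fold (4.45 to 4.63) higher. Ribosomal protein genes were lower in 28 of 30 (median -0.26) and the mitochondrially encoded median was -0.33. Beyond these, the EMT regulator gene SNAI1 was 8.06-fold (7.04 to 9.26) and the cell cycle inhibitor gene CDKN1A 7.71-fold (7.0 to 8.51) higher. GDF15 was 16.8-fold (15.2 to 18.6), PSG9 8.47-fold (7.59 to 9.47), ANKRD1 8.42-fold (7.38 to 9.65), PDK4 6.54-fold (5.82 to 7.37) and IGFL2-AS1 5.84-fold (5.59 to 6.11) lower. Of 8943 genes 9.3% lay more than 2-fold apart, 455 higher and 377 lower, or 388 and 613 with totals without mitochondrial and ribosomal protein genes.

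Set against untreated cells at 72 h, the recovery cells still had higher levels of ER stress genes. No untreated library was labelled for the time of recovery. HSPA5 was 6.47-fold (6.34 to 6.59) higher, HERPUD1 7.62-fold (7.46 to 7.78), DDIT3 7.29-fold (7.09 to 7.5) and the ER-resident growth factor gene MANF 3.07-fold (2.98 to 3.16). Sterol genes were above the untreated level too, with MSMO1 7.48-fold (7.22 to 7.76), INSIG1 7.07-fold (6.55 to 7.65) and HMGCS1 5.8-fold (5.53 to 6.09) higher. The proapoptotic gene BBC3, which encodes PUMA, was 8.78-fold (8.1 to 9.52) higher and CDKN1A 3.21-fold (3.01 to 3.43).

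ER chaperone genes were higher in 22 of 23 (median 0.75), PERK-ATF4 genes in 24 of 26 (median 0.53) and cholesterol genes in 19 of 23 (median 0.85), each median above 10000 random lists. PPP1R15A was 3.55-fold (3.41 to 3.7) and DDIT4, an inhibitor of mTORC1, 3.22-fold (3.17 to 3.27) higher. The fatty acid synthesis median was 0.14, above 9075 random lists, with ACSS2 3.17-fold (3.05 to 3.29), ELOVL5 2.59-fold (2.51 to 2.68) and SCD 2.28-fold (2.18 to 2.38) higher; ACACA was 1.75-fold (1.68 to 1.83) lower and ACACB stood at 3.78 against 3.5 CPM. S phase genes were lower in 31 of 38 (median -0.41, above 201 random lists), while the G2/M median was 0.10. Apoptosis and cell cycle arrest genes had a median of 0.32, above 9986 random lists, and NF-kB and cytokine genes one of 0.70, above 10000. Against the 0 h untreated library the PERK-ATF4 median was 1.36, the S phase median -1.17 and the apoptosis and arrest median 1.26. The stress chaperone genes HSPA1B, HSPA1A and DNAJB1 were 5.62-fold (5.4 to 5.85), 4.56-fold (4.47 to 4.65) and 4.09-fold (4.01 to 4.16) higher, though the heat shock median of 0.26 lay within the central 95% of random lists. Mitochondrially encoded genes had a median of -1.09, with 12 of 13 lower.

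Other genes named for recovery were GADD45G at 13.7-fold (12.7 to 14.7), the lipid transporter gene MFSD2A at 10.05-fold (9.0 to 11.2), SNAI1 at 9.92-fold (8.61 to 11.5), ZNF674-AS1 at 7.59-fold (6.94 to 8.32), the clock gene NR1D1 at 6.65-fold (6.14 to 7.22) and the phospholipase gene PLA2G2A at 5.71-fold (5.3 to 6.16) higher. The Wnt inhibitor gene DKK1 was 11.1-fold (6.92 to 18.9) lower, the cytokine gene LIF 10.7-fold (9.22 to 12.5), CCN2 10.6-fold (9.61 to 11.7), HMGA1P4 9.84-fold (8.73 to 11.1), STARD13 9.4-fold (8.48 to 10.4), RIMS2 10.2-fold (9.24 to 11.2), HECW2 7.22-fold (6.54 to 7.97), the endothelin gene EDN1 6.55-fold (6.18 to 6.96) and EID2 6.1-fold (5.53 to 6.73). DKK1 lay below 10 CPM in both libraries compared and was named through its level in the 0 h library, so its fold rests on few counts. Of 9405 genes 15.5% lay more than 2-fold apart, 425 higher and 1036 lower, against 789 and 536 with median-of-ratios scaling (a median shift of 0.28) and 745 and 558 with the trimmed mean of M values. Over genes of at least 50 CPM, 209 were higher and 200 lower. Against the 0 h untreated library 1095 were higher and 1256 lower, and 14 of 33 printed folds differed by more than 1.5 times, the most for DKK1 at a log2 ratio of -6.98 in place of -3.47.

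How far the differences seen at 72 h were still present in recovery was read from the genes named for 72 h, which had been chosen with both untreated libraries. Recovery was read against those same libraries, which by itself favours the same direction. The values below thus describe these genes and do not test persistence. The 10 highest had a median log2 ratio of 2.76 at 72 h of inhibitor against 72 h untreated cells. In recovery their median was 2.46 against 0 h cells, with 10 higher, and 1.52 against 72 h untreated cells, with 9 higher. GDF15 was the exception, at 4.15 against 10.1 CPM. Between the untreated libraries the same genes had a median of 0.81. The 10 lowest had a median of -3.03 at 72 h. In recovery it was -0.91 against 0 h cells, with 9 lower and S100A9 higher, at 9220.2 against 6076 CPM, and -0.96 against 72 h untreated cells, with 10 lower. Between the untreated libraries it was 0.22.

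**Figure D2:**
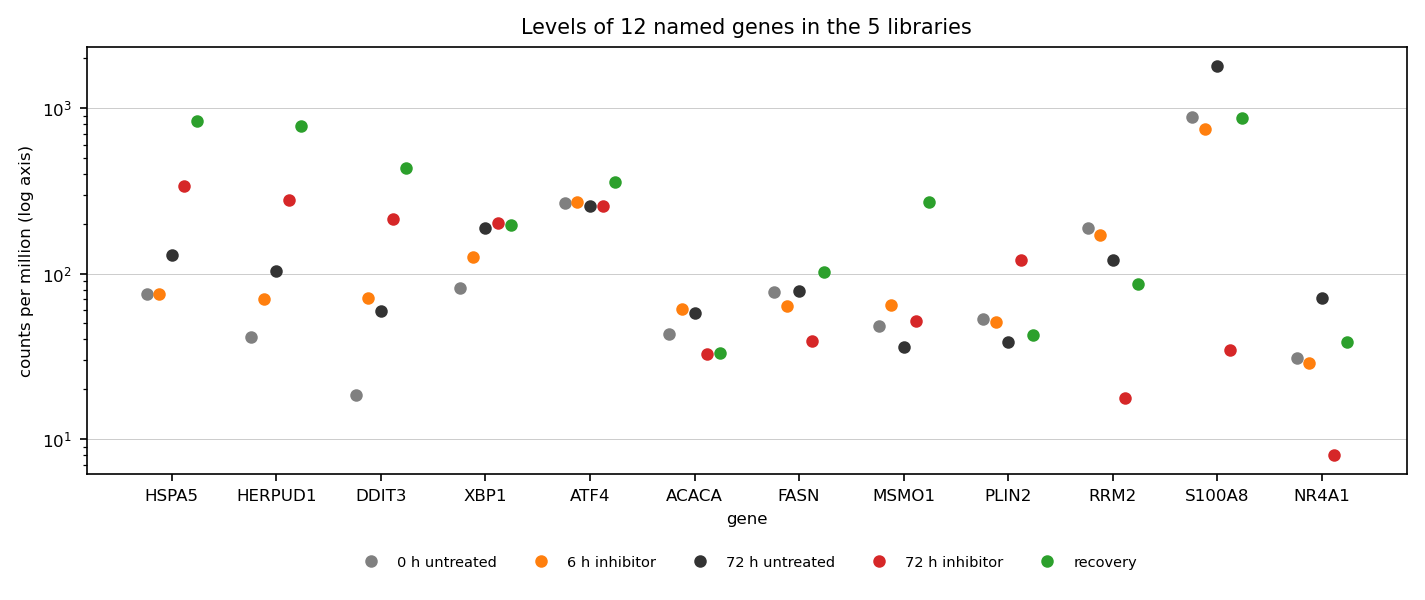
Levels of 12 named genes in CPM (log axis), 1 point per library. HSPA5 stood at 74.8 in the 0 h untreated library, 340.4 at 72 h of inhibitor and 838 in recovery.

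The last comparison, of untreated cells at 72 h against 0 h, asked how libraries without inhibitor differed. ER stress genes were higher after 72 h without inhibitor and S phase genes were lower. HSPA5 was 1.73-fold (1.68 to 1.78), XBP1 2.29-fold (2.24 to 2.35), DDIT3 3.22-fold (3.06 to 3.39) and DDIT4 4.28-fold (4.15 to 4.42) higher, while CLSPN, a replication checkpoint gene, was 2.64-fold (2.56 to 2.71) lower. The keratin gene KRT6A was 12.6-fold (11.3 to 13.9) lower and the interferon-induced gene BST2 5.36-fold (5.05 to 5.69) higher.

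ER chaperone genes were higher in 20 of 22 (median 0.30, or 0.038 with median-of-ratios scaling), PERK-ATF4 genes in 24 of 26 (median 0.73) and NRF2 targets in 15 of 16 (median 0.48). The PERK-ATF4 and NRF2 medians lay above 10000 of 10000 random lists and the ER chaperone median above 9821. S phase genes were lower in 40 of 40, with a median of -0.63, and cholesterol genes in 19 of 23, with a median of -0.52. Both medians lay below every matched random list, so such ranks also arose without inhibitor. INSIG1 was 2.31-fold (2.12 to 2.52), IDI1 2.09-fold (2.02 to 2.15) and SQLE 1.99-fold (1.91 to 2.07) lower. Basal epithelial genes had a median of -0.49 and interferon response genes one of 0.81, with all 10 measured members higher. The G2/M median of 0.073 turned to -0.19 with median-of-ratios scaling, and the mitochondrially encoded median of 0.19 to -0.076. ACACA was 1.34-fold (1.29 to 1.39) higher and ACACB 1.32-fold (1.15 to 1.52) lower. AKR1C3, NEURL3, LEMD1 and DMGDH were 7.15-fold (6.67 to 7.67), 6.38-fold (5.83 to 7.0), 6.29-fold (6.05 to 6.53) and 5.05-fold (4.66 to 5.48) higher. DKK1, OLFML3, the galanin gene GAL and PPP1R14B-AS1 were 11.4-fold (9.83 to 13.2), 10.5-fold (9.85 to 11.2), 8.22-fold (7.53 to 8.98) and 7.96-fold (7.39 to 8.59) lower. Of 9303 genes, 517 were more than 2-fold higher and 138 lower, against 225 and 308 with median-of-ratios scaling (a median shift of -0.28) and 237 and 279 with the trimmed mean of M values.

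Counts per cell showed whether these differences were spread over the cells, after each cell of at least 5000 UMIs was thinned to that number. The median cell held 10 UMIs of the ER chaperone list at 0 h untreated, 9 at 6 h of inhibitor, 13 at 72 h untreated, 15 at 72 h of inhibitor and 26 in recovery. The share of cells above the 90th percentile of the 0 h library for that list was 7.46% in that library itself, since counts tie at the percentile. It was 4.31% (3.61 to 5.1) at 6 h, 21.5% at 72 h untreated, 40.7% (38.4 to 43) at 72 h of inhibitor and 87.1% (86 to 88.2) in recovery. For PERK-ATF4 genes the shares were 40.6% (38.8 to 42.3), 46.9% (45.1 to 48.7), 86.7% (85.1 to 88.2) and 88.3% (87.2 to 89.4) in the same order, and 8.97% at 0 h. A cell drawn from recovery held more ER chaperone UMIs than one drawn from 72 h of inhibitor with a probability of 0.821, and more PERK-ATF4 UMIs with a probability of 0.559. Cholesterol gene shares were 8.34% (7.38 to 9.39), 1.66% (1.23 to 2.2), 0.696% (0.371 to 1.19) and 28.8% (27.3 to 30.4), beside 8.35% at 0 h. Those of fatty acid synthesis genes were 7.44% (6.53 to 8.44), 13.7% (12.5 to 15), 4.28% (3.41 to 5.3) and 27.9% (26.4 to 29.4), beside 7.49%. S phase gene shares were 7.24% (6.34 to 8.23), 1.18% (0.818 to 1.64), 0.161% (0.0331 to 0.469) and 0.116% (0.0315 to 0.296), beside 9.59%, and G2/M gene shares 10.01% (8.96 to 11.1), 12% (10.8 to 13.2), 4.82% (3.89 to 5.89) and 15.6% (14.4 to 16.9), beside 9.89%.

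**Figure D3:**
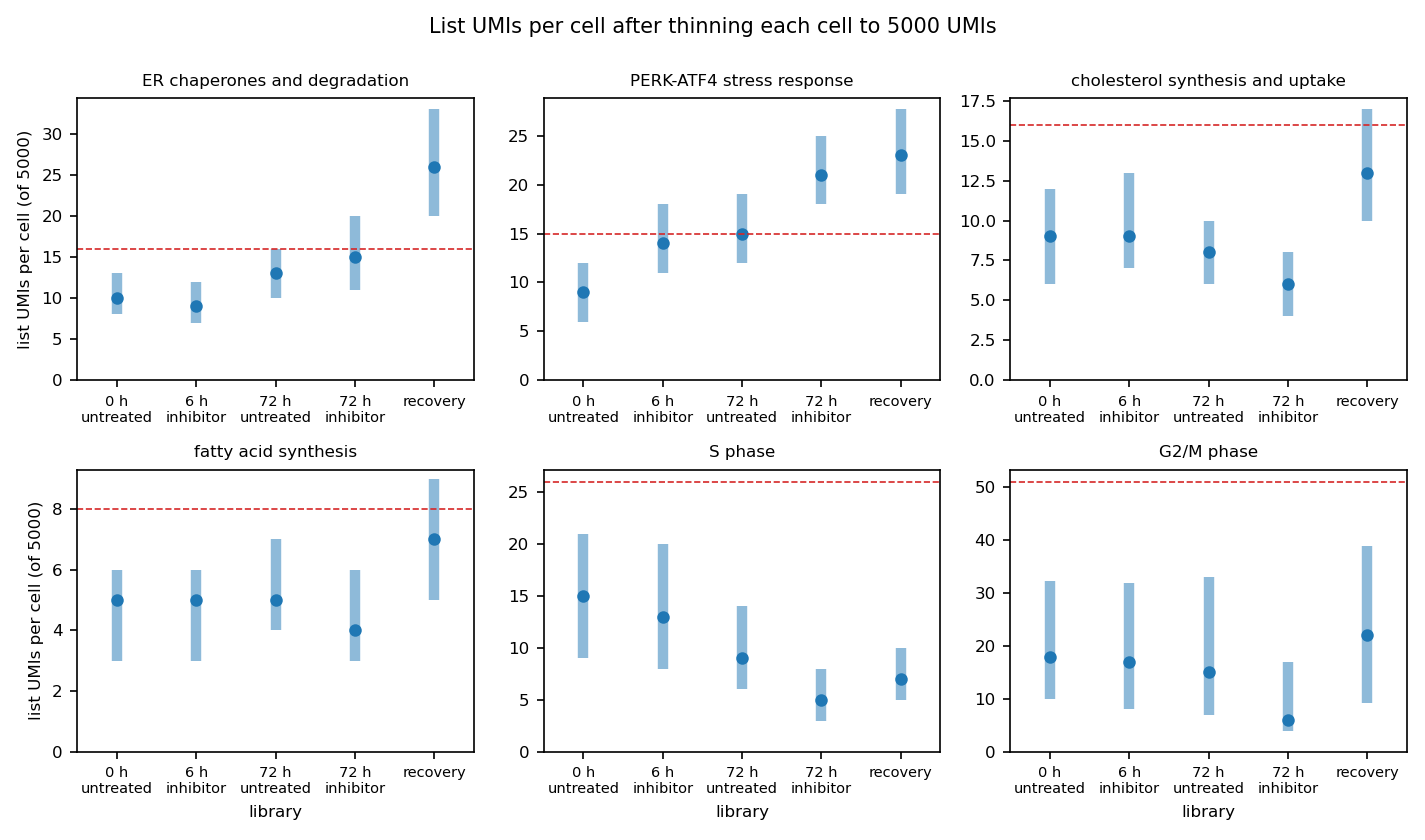
UMIs of 6 gene lists per cell (vertical axes, of 5000 UMIs per cell) in the 5 libraries: points are medians, bars run between the quartiles, and dashed lines mark the 90th percentile of the 0 h untreated library. The median cell of the recovery library held 26 ER chaperone UMIs and 23 PERK-ATF4 UMIs, against 10 and 9 at 0 h.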

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

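Of the tests below, the one in cells of at least 20000 UMIs was chosen only after the data were seen. Genes of ER chaperones and ER-associated degradation lay on opposite sides of untreated cells at the early and late time, with medians of -0.12 at 6 h and 0.39 at 72 h of inhibitor. Mitochondrially encoded genes did the reverse, with medians of 0.29 and -0.99, but their 6 h median was 0.026 against the 72 h untreated library. Neither difference between the times was tested, since each time had 1 inhibitor library. Barcodes left out by the cell filter made up 6.32% of the 72 h inhibitor library and 3.86% of the recovery library, against 0.83% at 0 h and 2.5% at 72 h untreated.

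ER chaperone genes were higher in recovery than under the inhibitor, although the inhibitor library was itself above untreated cells. Damaged or shallow cells were weighed first, with each cell counted equally. This measure replaced the list median of summed counts in the same cells, which had been set down earlier and is not given here. Among cells of at least 20000 UMIs and at most 10% mitochondrial UMIs, a recovery cell was compared with a 72 h inhibitor cell. It held more ER chaperone UMIs with a probability of 0.832, against 0.821 among all cells. The difference was thus present among these deeper cells too. They were 2481 of 3462 recovery cells and 1657 of 1868 inhibitor cells. With so large a share their value could not lie far below that of all cells, which leaves damaged cells open. A different mix of cell cycle stages was weighed next. In cells low in both cell cycle lists the ER chaperone median log2 ratio was 0.54, against 0.59 in all cells. The G2/M median between these cells was still 0.72, against 1.15 in all cells. The setting thus did not even out the cell cycle and cannot decide. Handling of the libraries and time in culture cannot be told apart from recovery. Each group is 1 library, and no untreated library was labelled for the time of recovery. The untreated libraries alone, which differed in time as well, were apart by a median of 0.30. A stress response that continued or grew after the inhibitor may explain the difference. It stays open beside handling, time in culture, the mix of cell cycle stages and damaged cells.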

How the results depend on the processing

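Of 1476 recomputed list medians, 1373 stayed within the main median's interval, 99 moved beyond it and 4 changed sign from a median outside the central 95% of its random lists. Counting medians near 0 too, 1357 kept their sign. These counts pool settings that could hardly move a median. At 72 h of inhibitor, no cell filter moved the median of all genes by 4.1e-04 and the 10% mitochondrial limit by -0.0017. Of 2156 recomputed ratios of printed genes, 2136 kept their sign and 768 moved beyond their counting interval, by up to 3.51 on the log2 scale. The setting with cells of at least 20000 UMIs was chosen only after the data were seen. Removal of cells called by Scrublet was not run, because it called fewer than 0.5% of cells in every library. LXR targets, mesenchymal genes and markers of other cells had no median where fewer than 5 members were measured. The cause was not tested for the differences below, with a few exceptions. Thinning to 10000 UMIs gives more counts per cell, and no minimum adds genes of few counts. With no cell filter the thinning was drawn anew. Ratios of genes below 10 CPM rest on fewer counts.

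With median-of-ratios scaling, the S phase median was -0.49 at 72 h of inhibitor, -0.24 at 6 h, -0.15 in recovery against 72 h untreated cells and -0.89 between the untreated libraries. G2/M medians were -0.14 at 6 h, 0.36 in recovery against 72 h untreated and -0.19 between the untreated libraries. ER chaperone medians were -0.29 at 6 h and 0.038 between the untreated libraries, where the PERK-ATF4 median was 0.46 and the mitochondrially encoded one reversed to -0.076. With the trimmed mean of M values, S phase medians were -0.51, -0.21, -0.17 and -0.86 in the same order. G2/M medians were -0.11, 0.34 and -0.16, and ER chaperone medians -0.25 and 0.062. The mitochondrially encoded median reversed to -0.051.

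In cells low in both cell cycle lists, G2/M medians were -0.062 at 72 h of inhibitor, -0.29 at 6 h, 0.72 in recovery against 72 h of inhibitor, 0.38 in recovery against 72 h untreated and -0.075 between the untreated libraries. The S phase median between the untreated libraries was -0.47, the cholesterol median at 6 h 0.23 and the share of genes more than 2-fold apart at 6 h 3.75%.

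Against the other untreated library, medians at 72 h of inhibitor were -0.61 for cholesterol genes, 0.74 for ER chaperones, 0.98 for PERK-ATF4 and -1.32 for S phase. At 6 h they were 0.47, -0.38, 0.19 and, reversed, 0.57, and HERPUD1 and XBP1 reversed to -0.55 and -0.58. In recovery they were 1.19 for ER chaperones, 1.36 for PERK-ATF4 and -1.17 for S phase. Shares of genes more than 2-fold apart were 18.8% at 72 h, 5.98% at 6 h and 25.4% in recovery. With no expression minimum they were 22.1% at 72 h, 8.74% at 6 h, 19.8% in recovery against 72 h of inhibitor, 29% against 72 h untreated and 20.5% between the untreated libraries. Over genes of at least 50 CPM the hypoxia median at 6 h reversed to -0.048.

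With cells thinned to 10000 UMIs, the share of cells above the 0 h 90th percentile for ER chaperones was 5.32% at 6 h, 52.2% at 72 h of inhibitor, 32.6% at 72 h untreated and 94.7% in recovery. For PERK-ATF4 genes it was 51.7%, 94.9%, 60.5% and 96%. At 6 h, 72 h untreated and in recovery it was 10.7%, 1.08% and 35.2% for cholesterol genes and 9.27%, 19.2% and 38.4% for fatty acid synthesis genes. For S phase genes it was 0.525% at 72 h untreated. With no cell filter, the fatty acid synthesis share at 6 h was 5.96%. Cells above the percentile fell from 223 of 2996 to 179 of 3001. Added cells cannot lower that count, so the move came from the random thinning, which was drawn anew.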

Other observations

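The lists of snoRNA host genes, decay factor genes and nuclear RNAs were chosen only after the data were seen, as was the test of long genes in cells of at least 20000 UMIs. Host genes of small nucleolar RNAs, whose spliced transcripts are degraded by nonsense-mediated decay, were higher after 72 h of inhibitor. SNHG12 had a log2 ratio of 2.80 and SNHG1 one of 1.91. All 13 genes of the list were higher, with a median of 1.51, and the 9 not seen beforehand had one of 1.10. The median of the whole list was 0.94 in recovery against 72 h untreated cells, 0.079 at 6 h and 0.43 between the untreated libraries.

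Many of these host genes share a 5' sequence motif with ribosomal protein genes. The median of the 9 genes not seen beforehand exceeded that of ribosomal protein genes by 0.54, but its interval of 0.39 to 1.79 includes the ribosomal protein median of 0.56, so a shift shared by both classes stays open. Lower nonsense-mediated decay may account for the difference too. Genes of the decay factors, which are themselves decay targets, had a median of 0.20 at a percentile of 95.9, with 6 higher and 2 lower, which left this open.

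Genes with long genomic spans were higher in the 6 h inhibitor library than at 0 h. Genes were ranked by span and split into 10 equal groups. The group of longest spans, 873 genes starting at 172 kb, had a median of 0.48 and the group of shortest spans one of -0.20. More nuclear RNA per UMI may explain it, since the nuclear RNAs measured had a median of 0.91, with MALAT1 at 1.06, NEAT1 at 0.91 and OIP5-AS1 at -0.063. MALAT1 was 1.89 in recovery against 0 h, where the group of longest spans had a median of -0.18, and the untreated libraries alone had a gap of 0.39, so a trait of the 0 h library stays open too. In cells of at least 20000 UMIs and at most 10% mitochondrial UMIs the gap was 0.67, against 0.68 in all cells. That setting kept 2859 of 3006 and 3376 of 3705 cells and so moved little, which leaves damaged cells open.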
